A study of Danio rerio with 8 samples.

How the data were processed

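The 8 arrays comprised GFP-positive and GFP-negative cells of cd41-GFP transgenic zebrafish embryos at 35 hours post fertilization, with 4 arrays per fraction. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, living cells were gated by dye exclusion, scatter and GFP, and each sorted population was passed through the sorter again for purity. The RNA went through 2 rounds of linear amplification before hybridization to the Affymetrix zebrafish array. The protocol also mentions sorts from gata1-GFP and lmo2-GFP embryos, which were not analysed here.

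The deposited table holds 1 intensity value per probe set and array, on a linear scale. Per the submitters' processing notes these are MAS5 signals, and the version is not given in the sources used here. All values were above 0, and the mean without the lowest and highest 2 percent of probe sets lay between 1500.26 and 1500.47 on all arrays, so the deposited intensity values share 1 scaling and were used as they stand. Scanner files and detection calls were not used here. No pair of arrays held identical values.

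Of 15617 probe sets, 115 were Affymetrix controls and stayed out of the tests. Probe sets were named through the platform annotation supplied with the table, with symbols updated by gene identifier. Over all probe sets, 10802 had 1 gene symbol, 135 had several and 4680 had none. Probe sets with several symbols or none were tested but not named. No genome coordinates were used, because the annotation names no build for these probe sets.

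Signals were transformed to log2 without a pseudocount. A probe set was tested if its signal was above the 40th percentile of its array on at least 4 of 8 arrays, which left 9801 probe sets with 6541 symbols. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression, two-sided), and p-values were adjusted by Benjamini and Hochberg over all tested probe sets, with a threshold of 0.05. The replicate number entered as a block, because the design text states that the fractions were paired before the statistics. A check of the pairing in the data gave correlations of the deviations from the group means within a pair of 0.40, 0.26, 0.18 and -0.12, so in pair 4 the data do not show the pairing, and it rests on the design text. Beside this, a fit with no replicate block called 1191 probe sets higher and 1688 lower. Differences are GFP-positive minus GFP-negative, and folds are 2 to the power of the log2 difference.

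A probe set below the 40th percentile on all arrays of a fraction was treated as dim there, and its fold is given as a lower bound, "at least N-fold". After the values were seen this was extended to probe sets above the percentile on only 1 or 2 of the 4 arrays of the lower fraction, and to the list medians given with dim genes at their bounds. For this bound the dim fraction was set to the mean of the higher of the percentile and the measured signal on each array. No such fold is given where both fractions were dim. These bounds rest on mean signals and leave out the spread between arrays, so they are not confidence limits. The 95% confidence interval can hold smaller folds. For cxcr4a, given as at least 4.16-fold lower, the limit of the log2 difference nearer 0 was -1.26, a smaller fold. Of the printed genes, those measured on 1 array of the lower fraction were bhlhe22, blnk, crestin, cxcl12a, cxcr4a, gbx1, gng3, grna.1, hoxb3a, hsd3b7, irf1b, irf7, matn1, myl1, nr4a1, pax2a, pou3f3b, rps6ka1, six6b, slc7a7, smyhc1, sp8b, sulf2a, tnfaip8l2a and vsir, and those measured on 2 were cxcl12b, ift57, irx1a, myhz1.3, pdia2, ptgs1, slc1a2b, socs3a, sox19a and zic2b. Those measured on 3 keep their fitted difference, namely anxa1c, apoc1, aqp3a, ctss2.2, dlb, foxd3, gata3, her9, hoxd4a, meis1b, rfc5, srgn, tnnc2.2 and tnnt2a. MAS5 signals of dim probe sets are noisy, and amplification shortens transcripts toward the 3' end. The ratio of the 3' to the 5' GAPDH control signal was 18.2 to 75.4 on GFP-negative and 31.3 to 100.0 on GFP-positive arrays, and it was higher on the GFP-positive array in 4 of 4 pairs. The ratio of the 3' to the middle signal was higher there in 3 of 4 pairs and lower in pair 2.

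The gene lists and the rule for named genes were fixed before the data were examined. The rule names 10 target genes, the 12 genes with the largest rise and the 12 with the largest fall among called probe sets moving the same way in all 4 pairs, and up to 4 members of each list with the smallest p. A gene with several tested probe sets was represented by the one with the highest mean signal. Of 697 genes with more than 1 tested probe set, 2 had called probe sets in both directions. Further probe sets that failed the filter did not pass for apaf1, coro1a, gng3, her4.5, hoxa9a, mpx (2 of 3), pax2a, ptpro, rfx2, s1pr1 and zic2b. Those of her4.5, hoxa9a, pax2a and rfx2 and 1 of 2 for ptpro pointed the other way. Some probe sets share their cluster number with a probe set of another gene, so their names are less certain. Among those printed these are anxa1c, apaf1, apoc1, apoeb, cox7a2a, dla, gng3, her4.5, hoxd4a, hsp90aa1.1, irf2bpl, lgals3b, mpx, psmd13, rfc5, s1pr1, sparc and tpma. Some members were named outside the rule after their values were seen: the members mpx, lyz, grna.1, gpx1a, hbae3, hbbe3, hbaa1, hbbe2, meis1b, hoxa9a, gata2a, tnnt2a, matn1, cxcr4a, atf3 and hsp90aa1.1. The targets itga2b, runx1 and cdh17 did not pass the filter, so their values come from a fit of all 15502 probe sets that are not controls, a departure from the planned design. The control probe sets were taken from a fit of all probe sets, controls included, and their p-values were adjusted over the 115 controls alone.

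Of 25 lists, 23 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists, with fry as a second test. Fry, which asks only whether the genes of a list move one way on balance, called 11 lists at an adjusted p of 0.05, the stem and progenitor and thrombocyte lists among them. The lists cover blood (stem and progenitor, thrombocyte, erythroid, haem biosynthesis, myeloid, lymphoid), vessels, pronephros, podocytes, motile cilia, other embryonic tissues and cell states. Single-gene counts per list were also adjusted over the list alone. With an estimated correlation none of the 23 lists was called, with a lowest adjusted p of 0.51. The pigment list lost its call too, though its estimated correlation of -0.0036 lay below the preset 0.01. These losses therefore cannot be put down to correlation within a list alone. The camera adjusted p of 0.51 was shared by lists not called at the preset correlation, such as stem and progenitor and thrombocyte. It therefore does not measure how firm any single list is.

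The procedure was tested on data simulated for this comparison, with 9801 probe sets and 50 changed probe sets per size. It recovered 14 percent of changes of log2 size 1, 76 percent of size 2 and 100 percent of sizes 3 and 4, with 8 false calls among 153. It called 10 of 10 shifted lists and 0 unshifted lists. Noise was drawn independently for each probe set, so genes of a simulated list were not correlated. In the data the estimated correlation was 0.64 in the myeloid and 0.78 in the neural list. The simulation therefore does not test list calls at such correlations. It also planted far fewer changes than the 3078 probe sets called in the data, and the cutoff after adjustment depends on that number. Its recovery rates therefore do not give the power of the real comparison.

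Alternatives fixed in advance were other scalings (quantile, cyclic loess, median centring), a pseudocount of 71.6, no filter and a stricter filter at the 60th percentile, no variance trend, array weights, each replicate left out, no block or a random block, and for the lists an estimated correlation and all probe sets of a gene. Leaving out replicates 1 and 3 together and centring on housekeeping lists were chosen after seeing the data.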

Results

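Gene expression was measured in zebrafish embryos of the AB background at 35 hours post fertilization. The embryos carried a cd41-GFP transgene, in which green fluorescent protein follows the promoter of itga2b (cd41), an integrin gene used as a marker of thrombocytes and of early blood stem and progenitor cells. Live cells were sorted by fluorescence into a GFP-positive and a GFP-negative fraction, and RNA of each fraction was hybridised to an Affymetrix zebrafish array after 2 rounds of linear amplification. There were 4 arrays of each fraction, paired by sort as replicates 1 to 4. The series title names haematopoietic stem cells in development, so the question is which genes differ between the sorted cells and the rest of the embryo. The labels do not say whether the sorts came from separate clutches, so p-values measure the spread between these samples, which may be technical. Precision is limited by the number of arrays. All arrays had the same trimmed mean signal, 1500.26 to 1500.47, and their median signals ran from 278 to 424.

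The fraction labelled GFP-positive carried high levels of myeloid transcripts and low levels of transcripts of muscle, the nervous system and connective tissue. The gene of the myeloid transcription factor Pu.1, spi1b, was 33.9-fold higher in this fraction, with a log2 difference of 5.08 (SE 0.38, n = 4 pairs, adjusted p = 0.00064). Of 22 tested myeloid genes 21 rose and 0 fell, while 40 of 44 neural genes and 23 of 30 muscle genes fell. Of 24 erythroid genes 16 fell and 1 rose, and of 15 endothelial genes 8 fell and 0 rose, gata1a and kdrl being among the fallen. No list call held with an estimated correlation between genes. In all, 1273 of 9801 tested probe sets were higher and 1805 were lower on the deposited scale. The balance of the directions depends on the scaling, with 1428 higher and 1550 lower after quantile normalization and 1496 higher and 1440 lower after median centring.

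The genes named in advance for this gate did not move together. The gene behind the gate, itga2b (probe set DrAffx.1.8.S1_at), did not separate the fractions. Its log2 difference was 0.29 (SE 0.71, adjusted p = 0.80), it was higher in 3 of 4 pairs and ran from -0.42 to 1.00 with 1 pair left out, and its signal lay below the 40th percentile of the array on all 8 arrays. The labels of the fractions are therefore not checked by this gene. The control probe set for destabilised enhanced GFP, AFFX-Dr-pd2EGFP_at, was higher in the GFP-positive fraction in 4 of 4 pairs by 1.09, which did not pass the test (adjusted p = 0.27). The 18 probe sets of the hybridization spike-ins, which are added to each sample, were also higher in 4 of 4 pairs, by 0.86 to 1.53 (lowest adjusted p = 0.097), so 1.09 lies within the range of the spike-ins and cannot be read as GFP. The stem cell transcription factor runx1 was also dim on all arrays and differed by 1.46 (SE 0.84, adjusted p = 0.25), which rests on a GFP-negative log2 signal of 2.02 in replicate 1, and was 0.37 without that pair. The progenitor transcription factor myb was higher in 4 of 4 pairs by 0.68 (SE 0.32, adjusted p = 0.15), which did not pass either. The pronephric cadherin cdh17 was dim on all GFP-negative arrays and differed by 0.57 (SE 0.49, adjusted p = 0.44), or by 0.18 without pair 3.

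Among the other genes named in advance, spi1b rose and the remaining ones fell. Mean signals of spi1b were 11816 in the GFP-positive and 349 in the GFP-negative fraction, and another spi1b probe set rose less, by 3.98 (adjusted p = 0.0040). The erythroid transcription factor gata1a fell by 1.62 on the log2 scale (SE 0.31, adjusted p = 0.0099), a call lost without replicate 2. The blood and vessel transcription factor tal1 fell by 1.34 (SE 0.31, adjusted p = 0.018), a call lost without replicate 2 or 4. Its partner lmo2 fell by 1.04 (SE 0.32, adjusted p = 0.044). That call was lost under every other scaling, with no variance trend and without replicate 2, 3 or 4. The vessel receptor gene kdrl fell by 1.90 (SE 0.32, adjusted p = 0.0073). All 4 of these were lower in 4 of 4 pairs. The thrombopoietin receptor gene mpl had no probe set in the annotation used here.

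**Figure D1:**
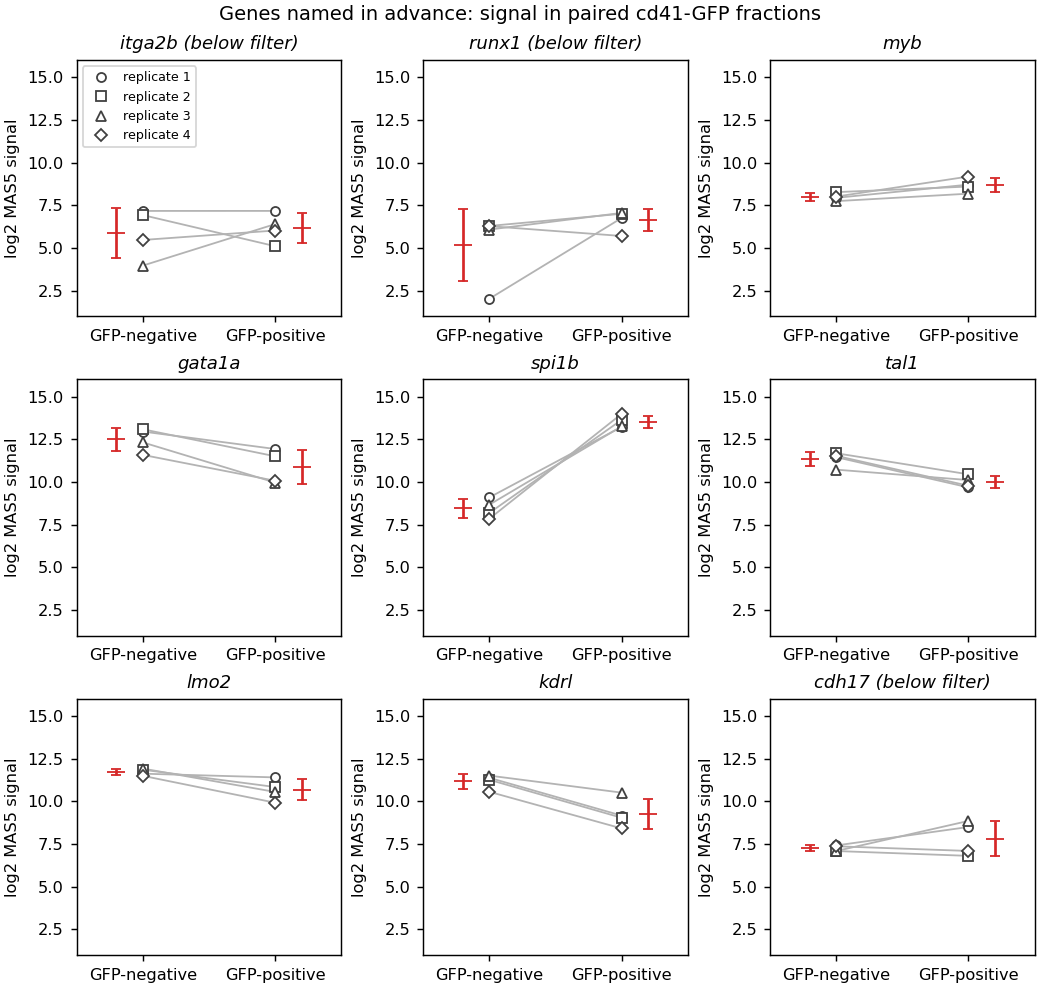
Log2 MAS5 signal (vertical axis) of the 9 genes named in advance that had a probe set, in the GFP-negative and GFP-positive fractions; lines join the fractions of a pair, and red marks give the mean and SD of 4 arrays. The lines of spi1b all rise steeply, those of gata1a, tal1, lmo2 and kdrl all fall, and those of itga2b cross.

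The 12 genes taken for the largest fitted rises included single genes of leukotriene synthesis, matrix breakdown, NF-kB inhibition and MAP kinase feedback. Of these 10 were dim on at least 2 of 4 GFP-negative arrays, so they have only lower bounds and no measured order. The leukotriene synthesis gene alox5ap was at least 32.4-fold higher (adjusted p = 0.00034) and the matrix metalloprotease gene mmp9 at least 46.4-fold. The protein disulfide isomerase gene pdia2 was at least 41.8-fold higher. The signalling genes rgs13a (at least 13.3-fold) and cxcr3.3, a chemokine receptor (at least 8.62-fold), were dim on all GFP-negative arrays, as was antxr2a (at least 3.38-fold). The inhibitor of NF-kB nfkbiaa rose by 5.73 and the MAP kinase phosphatase dusp2 by 5.71. The others, dim on 3 of 4 GFP-negative arrays, were the nuclear receptor nr4a1 (at least 35.8-fold), hsd3b7 (at least 39.2-fold), tnfaip8l2a (at least 43.2-fold) and the immune checkpoint gene vsir (at least 30.4-fold).

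The 12 genes taken for the largest fitted falls included contractile genes. All were dim on at least 2 of 4 GFP-positive arrays, so they have no measured order either. The myosin light chain genes myl1 and mylz3 were at least 41.2-fold (adjusted p = 0.0029) and at least 16.7-fold lower, and the myosin heavy chain genes myhz1.3 and smyhc1 at least 25.5-fold and at least 12.0-fold. The transcription factor genes of the neural plate and brain sp8b, gbx1, sox19a and bhlhe22 were at least 15.2-fold, at least 9.73-fold, at least 27.5-fold and at least 13.3-fold lower. The glutamate transporter gene slc1a2b was lower as well, and the sulfatase gene sulf2a was at least 12.4-fold lower. The Notch target her4.5 was at least 11.5-fold lower and the adenylate kinase gene ak1 at least 7.38-fold lower.

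Myeloid genes formed the list with the largest shift. Their median log2 difference was 4.05 (4.00 with dim genes at their bounds), all 22 tested genes but grna.1 rose (21 genes also when adjusted over the list alone), and the median was higher in 4 of 4 pairs, between 2.85 and 5.43. The list was called by camera (adjusted p = 3.3e-17; adjusted p = 0.51 with an estimated correlation). The Wiskott-Aldrich gene wasb rose by 3.62, the actin regulator coro1a by 4.61, and the amino acid transporter slc7a7 was at least 19.4-fold higher. The neutrophil peroxidase gene mpx rose by 3.89, and the lysozyme gene lyz by 2.57. The change of grna.1 did not pass (adjusted p = 0.12).

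Erythroid genes shifted the other way. Of 24 tested members 16 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -1.50 (camera adjusted p = 0.00022; adjusted p = 0.51 with an estimated correlation). The enzyme gene nt5c2l1 fell by 2.37, the membrane skeleton gene epb41b by 2.32, znfl2a by 1.82 and the biliverdin reductase gene blvrb by 1.75. The member that rose was the glutathione peroxidase gene gpx1a (2.08), which is not specific to red cells. The globin genes hbae3 (0.77, and -1.32 by another probe set) and hbbe3 (0.33) did not pass, while hbaa1 and hbbe2 fell by 1.23 and 1.90. In the haem biosynthesis list 4 of 9 members fell (5 adjusted over the list alone), namely fech, cpox, alas2 and alad, by 1.68, 1.40, 2.53 and 1.48, of which fech lost its call with no replicate block and cpox and alad lost it after median centring. That list was not called (median -1.40, camera adjusted p = 0.064).

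The stem and progenitor list and the thrombocyte list moved both ways and were not called by camera. Fry, which asks only whether the genes of a list move one way on balance, called both upwards (adjusted p = 0.033 each). In the first, 6 of 18 members rose and 7 fell (7 and 7 adjusted over the list alone), with a median of 0.13 and a camera adjusted p of 0.30. Its median was below 0 in 3 of 4 pairs and ran from -0.13 to 0.89 over the alternatives. Its risen members included the leukocyte phosphatase gene ptprc (4.69), cebpa (4.06) and fli1rs (2.98), and spi1b and cebpa are also in the myeloid list. Its fallen members included meis1b (-3.72), gata2a (-1.49) and hoxa9a, which was at least 1.70-fold lower. In the thrombocyte list 3 of 6 members rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.96 (0.46 to 2.302 over the alternatives) and a camera adjusted p of 0.24. The proteoglycan gene srgn rose by 4.76, the coagulation factor gene f13a1b by 2.302, and the cyclooxygenase gene ptgs1 was at least 5.199-fold higher, while thbs1b was at least 2.25-fold lower. The lymphoid list had 3 tested members and no list test. Of these blnk rose (at least 2.08-fold), gata3 fell (-1.52) and ikzf1 did not pass (0.64). The calls of blnk and gata3 were lost with no replicate block, under quantile normalization and without replicate 2 or 4, and ikzf1 became called without replicate 1.

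Endothelial genes fell in 8 of 15 cases and rose in 0 (8 and 1 adjusted over the list alone). The median was -1.34 (camera adjusted p = 0.028; adjusted p = 0.51 with an estimated correlation), and without the filter on dim probe sets the call was lost. The venous transcription factor nr2f2 fell by 3.39, the chemokine gene cxcl12b was at least 9.14-fold lower, and the sphingosine phosphate receptor gene s1pr1 fell by 2.73, while another s1pr1 probe set, dim in both fractions, differed by -0.32. In the pronephric list 10 of 16 members fell and 1 rose, also when adjusted over the list alone, and the list was not called (median -1.47, or -1.31 with dim genes at their bounds, camera adjusted p = 0.12). The transcription factor genes pax2a, pou3f3b and irx1a were at least 5.51-fold, at least 9.06-fold and at least 7.94-fold lower, and the aquaporin gene aqp3a rose by 2.46. Of 4 tested podocyte genes foxc1a, podxl and ptpro fell and cd2ap rose, without a list test. Of 10 motile cilia genes 2 fell, ift57 and rfx2 (also 2 adjusted over the list alone), with a median of -0.80 (-0.71 with dim genes at their bounds and -0.997 to 0.092 over the alternatives) and a camera adjusted p of 0.39. Neither fall is firm: ift57 lost its call with no replicate block, after housekeeping centring and without replicate 2 or 4, and rfx2 lost it under quantile normalization, cyclic loess and housekeeping centring and without replicate 2, 3 or 4. Another rfx2 probe set, dim in both fractions, was higher in 4 of 4 pairs.

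**Figure D2:**
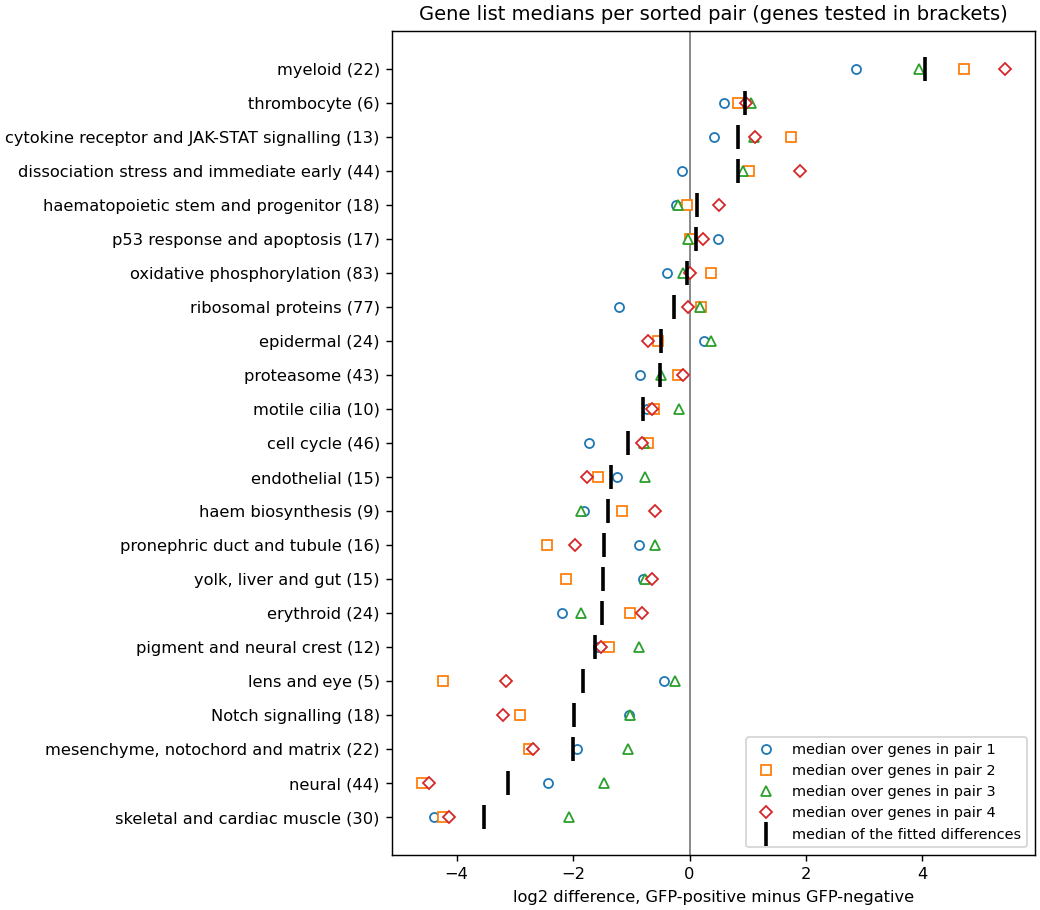
Median log2 difference, GFP-positive minus GFP-negative (horizontal axis), of the 23 tested gene lists, for each of 4 pairs (open symbols) and over the fitted differences (black bars). The myeloid list stands between 2.85 and 5.43 in the single pairs, and the neural and muscle medians of pair 3 lie nearest to 0 among the pairs.

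Neural and muscle genes were low in the GFP-positive fraction. In the neural list 40 of 44 genes fell and 0 rose (43 and 0 adjusted over the list alone), with a median of -3.12 (camera adjusted p = 2.5e-12; adjusted p = 0.51 with an estimated correlation). The radial glia gene fabp7a fell by 3.15, gng3 and zic2b were at least 19.2-fold and at least 13.1-fold lower, and the proneural gene neurog1 was at least 3.11-fold lower. In the muscle list 23 of 30 genes fell and 1 rose (26 and 2 adjusted over the list alone), with a median of -3.53 (camera adjusted p = 5.3e-09; adjusted p = 0.51 with an estimated correlation). The creatine kinase gene ckma fell by 4.43, tpma by 4.19 and tnnc2.2 by 4.98, while the troponin gene tnnt2a rose by 1.91. With dim genes at their bounds the neural and muscle medians were -2.71 and -2.42. The array of GFP-positive replicate 3 stood nearer the GFP-negative arrays than the others did, and in its pair the neural median was -1.48 and the muscle median -2.08. The muscle actin control signal was 1136 on that array and 202 to 383 on the other GFP-positive arrays, against 7297 to 19101 on the GFP-negative arrays. The 3' to 5' ratio of GAPDH, a sign of RNA shortening, was higher on the GFP-positive array in 4 of 4 pairs, and the ratio of the 3' to the middle signal in 3 of 4.

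In the list of mesenchyme, notochord and matrix 19 of 22 genes fell and 1 rose, also when adjusted over the list alone. Its median was -2.001, or -1.89 with dim genes at their bounds (camera adjusted p = 7.8e-06; adjusted p = 0.51 with an estimated correlation). The matricellular gene sparc fell by 3.16 and foxd3 by 2.58, prrx1a and prrx1b were at least 5.53-fold and 7.34-fold lower, and the cartilage matrix gene matn1 was at least 2.297-fold higher. In the list of pigment cells and neural crest 8 of 12 genes fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -1.62. Its call was marginal (camera adjusted p = 0.049, or adjusted p = 0.51 with an estimated correlation). It held in 8 of 16 alternatives other than the estimated correlation, and was lost with no replicate block or with either change of filter, among others. The crest gene crestin was at least 6.21-fold lower, while rab32a and mitfa rose by 3.28 and 1.62.

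The remaining tissue lists were not called. Of 24 epidermal genes 5 fell and 2 rose (6 and 3 adjusted over the list alone), with a median of -0.50 (-0.43 with dim genes at their bounds) and a camera adjusted p of 0.87. The keratin gene krt5 fell by 1.23, a call lost under every other scaling, and anxa1c by 2.14, and ponzr1 rose by 3.46, while another ponzr1 probe set did not pass (1.25, adjusted p = 0.051). The other risen probe set is named lgals3b (1.60). Of 5 lens and eye genes vsx1 (at least 1.96-fold lower) and six6b (at least 2.99-fold lower) fell, 2 also when adjusted over the list alone. The list median was -1.83 (-0.97 with dim genes at their bounds), with a camera adjusted p of 0.29. The call of six6b was lost after housekeeping centring and without replicate 2, 3 or 4. Of 15 yolk, liver and gut genes 6 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -1.48 (-0.90 with dim genes at their bounds) and a camera adjusted p of 0.24. The apolipoprotein genes apoeb and apoc1 fell by 2.48 and 3.04, and the transferrin gene tfa rose by 2.39.

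**Figure D3:**
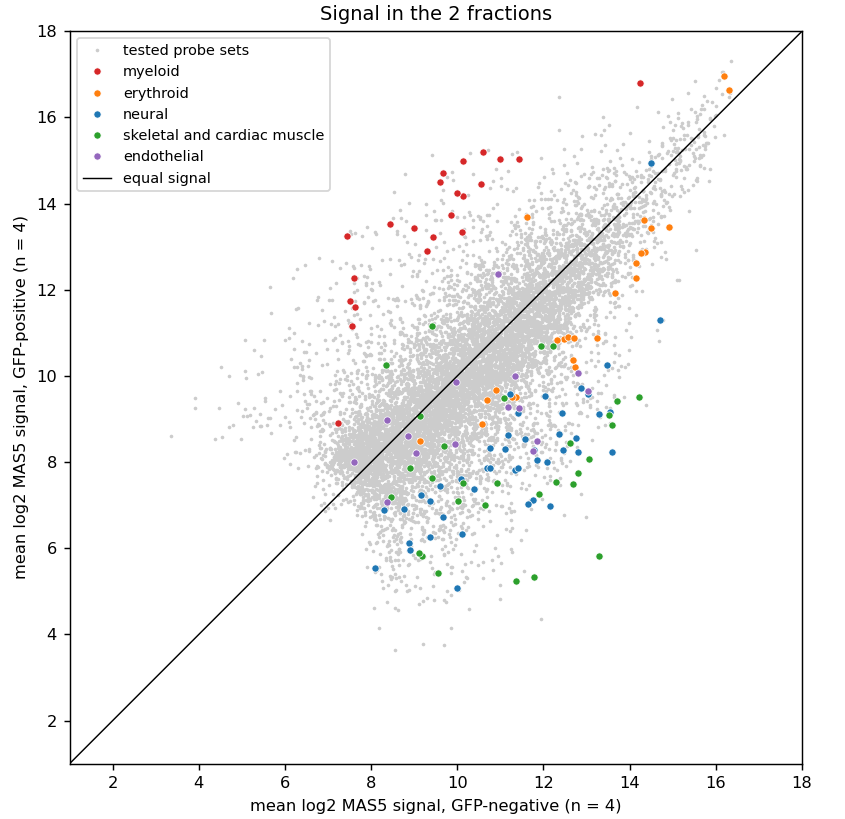
Mean log2 MAS5 signal of each tested probe set in the GFP-negative (horizontal axis) and GFP-positive fraction (vertical axis), n = 4 arrays each, with 5 gene lists in colour and the line of equal signal in black. The 22 myeloid genes lie above the line, and most neural, muscle and erythroid genes lie below it.

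Several lists of cell states shifted too. Cell cycle genes fell in 19 of 46 cases and rose in 0 (27 and 0 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 1.1e-05; adjusted p = 0.51 with an estimated correlation). The replication genes lig1, rfc5, cdc6 and pola2 fell by 1.59, 1.81, 1.38 and 1.46. In the Notch list 11 of 18 genes fell and 0 rose, also when adjusted over the list alone, with a median of -1.98, or -1.79 with dim genes at their bounds (camera adjusted p = 0.0029; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.068). Its leading members her9, dla, dlb and lfng fell by 3.67, 4.18, 4.17 and 3.39, and dla and dlb are also in the neural list. Another dlb probe set, dim in the GFP-positive fraction, did not pass (adjusted p = 0.065).

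In the list of cytokine receptors and JAK-STAT signalling 6 of 13 genes rose and 2 fell (7 and 2 adjusted over the list alone). The median was 0.84, with 0.78 to 1.38 over the alternatives (camera adjusted p = 0.0049; adjusted p = 0.51 with an estimated correlation). The feedback inhibitors socs3a and socs3b rose, at least 31.7-fold and by 3.61, the chemokine receptor gene cxcr4b by 2.43 and the phosphatase gene ptpn6 by 4.45, while cxcr4a was at least 4.16-fold lower. Of these genes, ptpn6 is also in the myeloid list, and socs3a and socs3b are also in the stress list. The shift of this list is therefore partly shared with those lists. In the list of dissociation stress and immediate early genes 17 of 44 rose and 3 fell (18 and 4 adjusted over the list alone). The median was 0.83, with 0.56 to 1.63 over the alternatives (camera adjusted p = 4.7e-05; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.068). It was higher in 3 of 4 pairs and -0.13 in pair 1. Besides socs3a, nr4a1 and nfkbiaa, the transcription factor genes fosl2 and atf3 rose by 3.25 and 3.53, and the chaperone gene hsp90aa1.1 fell by 1.52.

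Lists of general cell functions were not called. Of 17 genes of the p53 response and apoptosis 5 rose and 2 fell, also when adjusted over the list alone, with a median of 0.11 and a camera adjusted p of 0.24. The BH3-only gene pmaip1 rose by 3.16 and apaf1 by 1.92, while bcl2l10 fell by 1.65. The other fallen member was tp53inp1, a call lost without replicate 2 or 4. Of 77 ribosomal protein symbols 2 rose and 0 fell (1 and 0 adjusted over the list alone). Both were kinases taken in by the symbol rule, rps6ka1 (at least 12.2-fold) and rps6ka3a (1.48). The median of this list was -0.27 and its mean -0.16, while camera, which compares with the other genes, gave the upward direction (adjusted p = 0.75). Of 83 oxidative phosphorylation genes atp5if1b and cox7c rose by 1.95 and 1.15 and 0 fell (1 and 0 adjusted over the list alone), and cox7c lost its call under quantile normalization, cyclic loess and housekeeping centring. The median was -0.05, again with an upward direction by camera (adjusted p = 0.30). Of 43 proteasome genes psme2 rose by 0.89 and the assembly gene psmg2 fell by 1.18, none when adjusted over the list alone, with a median of -0.50 and a camera adjusted p of 0.17. Both calls ended with any 1 replicate left out, that of psme2 also with no block or a random block and that of psmg2 under every other scaling.

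Over all tested probe sets, 3078 passed the limma test at an adjusted p of 0.05, and 2913 of them differed at least 2-fold by the fitted difference, 1201 upwards and 1712 downwards. The 2-fold split was 1363 and 1479 after quantile normalization, 1390 and 1496 after cyclic loess, 1476 and 1413 after median centring, and 1147 and 1193 after housekeeping centring, a setting chosen after seeing the data. The median difference of all tested probe sets was -0.18, and no called difference lay between it and 0. The 1273 higher and 1805 lower probe sets therefore stand on the same sides of this median, without a new test. A new fit after median centring called 1496 higher and 1440 lower. Of the 1273 higher probe sets 1259 were higher in all 4 pairs, and of the 1805 lower ones 1788 were lower in all 4. The numbers also depend on replicates 2 and 4. Without replicate 2 there were 673 higher and 725 lower probe sets, and without replicate 4 there were 646 and 659.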

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

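The tests of carried-over cells, of exchanged fractions, of a lower share of other cells and of the dim itga2b probe set were chosen after the results they bear on had been seen in part, and the rule for matching genes in the first of them was revised after its first values were seen. The SEs under this heading come from resampling genes or probe sets, not arrays or pairs. They do not measure the spread between samples, and correlated genes can make them too small. Margins set in SE therefore describe variation among genes only.

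Among 283 groups of 4 values, 20 held 1 value far from the others by Dixon's test, where chance gives about 1 in 20. In GFP-negative replicate 1 the log2 signal of runx1 was 2.02 (others 6.07 to 6.28), of tnfaip8l2a 8.96 (7.49 to 7.63) and of nr4a1 9.16 (7.24 to 7.52). In GFP-negative replicate 4 sp8b stood at 13.12 (12.23 to 12.32), znfl2a at 11.72 (12.90 to 13.09) and nr2f2 at 13.35 (12.90 to 12.97), and in GFP-negative replicate 3 prrx1b stood at 9.95 (10.80 to 10.83). In GFP-positive replicate 1 fli1rs stood at 13.14 (12.12 to 12.20), blnk at 7.02 (9.16 to 9.55), rab32a at 11.83 (12.95 to 13.10), cox7a2a at 16.30 (13.25 to 13.69) and psmd13 at 8.35 (11.73 to 12.02). In GFP-positive replicate 3 slc7a7 stood at 11.22 (12.59 to 12.65) and sparc at 10.42 (8.88 to 9.12). Between pairs, the yolk, liver and gut median was -2.11 in pair 2 (others -0.80 to -0.64), and pair 1 had a cell cycle median of -1.72 (-0.81 to -0.72) and a ribosomal protein median of -1.20 (-0.02 to 0.20). The 3' to 5' GAPDH ratio was 75.4 on the array of GFP-negative replicate 1 (others 18.2 to 22.6).

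Control probe sets were not part of the comparisons. AFFX-Dr-AY056050-1_at, dim in the GFP-negative fraction, was at least 1.92-fold higher in the GFP-positive fraction (fitted difference 2.63, adjusted p = 0.019) and AFFX-Dr-U43284-1_s_at was higher by 2.08 (adjusted p = 0.020), each in 4 of 4 pairs and in the same direction under quantile normalization, median centring and housekeeping centring. Control probe sets of the hybridization spike-ins were higher too, all 18 in 4 of 4 pairs, by 0.86 to 1.53 (lowest adjusted p = 0.097). The fitted differences of the first 2 probe sets, 2.63 and 2.08, lay above this range, the former resting on a dim GFP-negative signal. What the first 2 probe sets detect is not named in the tables used here.

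The array of GFP-positive replicate 3 stood nearer the GFP-negative arrays (mean r over probe sets 0.79, other GFP-positive arrays 0.53 to 0.64), the muscle median of its pair was -2.08 (others -4.38 to -4.14), and its 100 brightest probe sets took 24.2% of the signal (others 19.1% to 19.9%). A shrinkage of all differences on this array is argued against: relative to the other pairs, risen genes kept a median ratio of 0.76 and fallen genes 0.38, a gap of 0.39 (0.32, SE 0.018, over probe sets above the 40th percentile on all arrays) where equal shrinkage predicts about 0. The gap rests on the pair of replicate 3 alone, and its SE is taken over probe sets. GFP-negative cells carried into this fraction may explain the pattern, since the excess of 5 embryo tissue lists over level-matched genes ran from 1.00 in the epidermal to 2.05 in the neural list. This stays open, because the lens list of 5 genes (1.39, SE 0.65) does not clear the limit of 0.25 by 2 SE, the margin used in these tests, although every list clears it by 1 SE. No biological explanation was tested.

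Myeloid genes rose while itga2b, the gene behind the gate, did not. An exchange of the fractions in some but not all pairs is argued against, because the myeloid median was higher in the GFP-positive fraction of 4 of 4 pairs. An exchange in all 4 pairs cannot be seen by this test. A lower share of other cells could raise all remaining blood and vessel genes alike. The myeloid median lay 5.40 (SE 0.60 over genes) above the endothelial median, so these 2 lists did not rise alike. The limit for this gap was set after list results had been seen, so it is not independent evidence. It also cannot judge a lower share of other cells where vessel cells are counted among them. In the single pairs the myeloid median ran from 2.85 to 5.43 and the endothelial median from -1.76 to -0.76. The itga2b probe set may be too dim to follow its transcript: its highest percentile on any array was 32.9, so whether the transcript differs cannot be told apart from a lack of signal. That the gate itself held many myeloid cells at this stage is a biological hypothesis these tests leave open.

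Of 44 dissociation stress and immediate early genes 17 rose in the GFP-positive fraction, with a median of -0.13 in pair 1 and no call by fry (adjusted p = 0.068). Handling stress could raise them, and heat shock and chaperone genes might then be raised too. Transcripts lost with other cells could hide such a rise, since hspb1 of the set as written is also in the muscle list. Their median over 8 genes was 0.10 (SE 0.44), too variable between genes to decide, against 1.102 over the 36 other genes of the list. A difference in the cells themselves, as named by the 2 fractions, stays open and untested.

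Without the block, 1 of 35 splits of the arrays, the real one, gave as many as 2879 changed probe sets, and the highest other gave 0. This argues against chance, though no smaller share is possible in this test and the splits ignore the pairing. With the block, 1 of 8 exchanges within pairs, the real one, gave as many as 3078, and the highest other gave 0, but 8 are too few for a share under 0.05.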

How the results depend on the processing

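Leaving out replicates 1 and 3 together and centring on housekeeping lists were tests chosen after seeing the data. No probe set called in the main setting changed sign under any alternative. The myeloid, erythroid, neural, muscle, mesenchyme, cell cycle, Notch, cytokine and stress lists kept direction and call in 16 of 16 alternatives other than the estimated correlation. With the estimated correlation these and the endothelial and pigment lists lost their calls at unchanged medians (4.05, -1.50, -3.12, -3.53, -2.001, -1.06, -1.98, 0.84, 0.83, -1.34 and -1.62; adjusted p = 0.51).

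Counts of higher and lower probe sets were 1968 and 3031 with array weights, and 1805 and 2799 without replicates 1 and 3. With 1 replicate left out they ran from 646 to 1466 and from 659 to 2027, and those changed at least 2-fold from 1305 to 2959. Fewer arrays alone do not account for this range, since without replicate 1 the counts rose to 1466 and 2027. No replicate block (1191 and 1688) and a random block (1392 and 2035) stayed within 1.5 times, and removing the block ended 1 list call, pigment (-1.62, adjusted p = 0.056), and among named genes 5 calls were lost and 1 gained.

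The itga2b difference turned negative, uncalled, under cyclic loess (-0.040), array weights (-0.60) and without replicates 1 and 3 (-0.63), and ran from -0.42 to 1.00 with 1 replicate left out. The cdh17 difference was -0.28 without replicates 1 and 3. The endothelial call was lost without the filter (-0.55). The pigment call was lost without the filter (-1.04), with the stricter filter (-1.63), no trend (-1.62), array weights (-1.44), without replicates 1 and 3 (-1.63) and without replicate 1 or 3 (range over replicates -1.70 to -1.45). Haem biosynthesis became called under cyclic loess (-1.32), no filter (-1.40), housekeeping centring (-1.25) and without replicate 1 or 4 (range -1.60 to -1.16). The pronephric list became called with median centring (-1.28) and without replicates 1 and 3 (-2.38), and oxidative phosphorylation with array weights (0.13) and without replicates 1 and 3 (0.17). Camera's direction turned for ribosomal proteins under quantile normalization (-0.61, adjusted p = 0.017; range over alternatives 0.017 to 0.97), cyclic loess (-0.42) and no filter (-0.26), and with 1 replicate left out the median ran from -0.42 to 0.10, called without replicate 1. It turned, uncalled, for epidermal genes under quantile normalization (-0.24) and the stricter filter (-0.36), with a range over replicates of -0.76 to -0.19. Where no cause is given, the cause was not tested.

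Medians of lists moved by over 1.5 times or turned for stem and progenitor (-0.13 to 0.89, negative without replicate 4), thrombocyte (0.46 to 2.302), motile cilia (-0.997 to 0.092, positive without the filter), stress (0.56 to 1.63), cytokine (0.78 to 1.38), erythroid (-1.68 to -0.998), endothelial (-2.04 to -0.55), haem (-1.60 to -0.89), pronephric (-2.38 to -0.35), epidermal (-0.84 to -0.19), lens (-3.66 to -0.81), pigment (-1.70 to -1.04), yolk (-1.92 to -0.72) and Notch genes (-3.09 to -1.54). The same holds for p53 (-0.01 to 0.30), ribosomal (-0.61 to 0.10), oxidative phosphorylation (-0.16 to 0.17) and proteasome genes (-0.60 to -0.25).

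Of the named genes, 22 lost their call without replicate 2, 22 without replicate 4 and 10 without replicate 3, and at most 9 under any other alternative. Those that lost it with no replicate block or under another scaling were alad, blnk, cox7c, cpox, fech, gata3, ift57, krt5, lmo2, psme2, psmg2, rfx2 and six6b. Those that lost it only with 1 replicate left out were alas2, anxa1c, apoc1, cdc6, foxa2, gata1a, irx1a, lgals3b, ptpro, rps6ka3a, sp8b, tal1, thbs1b and tp53inp1. Signal over background limits itga2b and runx1, dim on all 8 arrays.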

Other observations

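The gene families in this part, and their tests, were chosen after the data were seen. For this, 9 symbol patterns were written and 8 families had enough members to be tested by camera, integrins having 2 tested members. Vacuolar ATPase genes, which acidify lysosomes and phagosomes, rose in 11 of 15 cases and fell in 1 (median 1.57, adjusted p = 5.0e-05 over the 8 families; adjusted p = 0.32 with an estimated correlation). The accessory gene atp6ap1b rose by 2.98, and atp6v0cb fell by 2.15. Among genes of the Arp2/3 complex and capping protein, which build branched actin, 6 of 10 rose and 0 fell (median 1.97, adjusted p = 5.0e-05; adjusted p = 0.32 with an estimated correlation), among them arpc1b, also in the myeloid list, by 3.90 and arpc5b by 2.61. Of 10 cathepsin genes 5 rose and 1 fell (median 1.05, adjusted p = 0.0070; adjusted p = 0.43 with an estimated correlation), with ctss2.2 at 4.80 and ctsc at 3.05. Of 6 genes of NF-kB and its inhibitors 4 rose and 1 fell (median 1.67, adjusted p = 0.010; adjusted p = 0.32 with an estimated correlation). The pattern for interferon regulatory factors also took in irf2bp genes, which are not such factors. Of its 8 members irf7 (at least 11.2-fold), irf1b (at least 2.61-fold) and irf5 (at least 5.25-fold) rose and irf2bpl fell (adjusted p = 0.016; adjusted p = 0.32 with an estimated correlation).

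Of 21 hox genes 14 fell and 0 rose (median -2.37, or -1.25 with dim genes at their bounds, adjusted p = 0.00013; adjusted p = 0.43 with an estimated correlation), among them hoxb3a (at least 17.6-fold lower) and hoxd4a (-4.31). Of 15 collagen genes 9 fell and 1 rose (median -2.10, or -1.91 with dim genes at their bounds, adjusted p = 0.0072; adjusted p = 0.47 with an estimated correlation), several of them also in the mesenchyme list. Chemokine and receptor genes split, 3 of 8 rising and 5 falling, and were not called (adjusted p = 0.93). The chemokine gene ccl38a.5, dim in the GFP-negative fraction, was at least 7.35-fold higher, while cxcl12a was at least 4.32-fold lower. The directions of the 7 called families held under quantile normalization, cyclic loess, median centring and housekeeping centring, and that of the chemokine family turned under the first 3 of these.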
